A study of Homo sapiens with 26 samples.

How the data were processed

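RNA of the human breast cancer cell lines T47D and MCF-7, both derived from estrogen receptor-positive luminal tumours, was hybridised to 26 Agilent whole-genome expression arrays of 1 colour (green channel). Per the labels, the arrays formed 11 groups of 2 or 3 samples: wild-type T47D (n = 2), T47D kept in 100 nM fulvestrant for 36 weeks (n = 2), T47D population ED1 after 52 weeks without estrogen (n = 2), population ED2 after 62 weeks without estrogen (n = 2), ED2 given 1 nM estradiol for 24 weeks (n = 2) or 38 weeks (n = 2), wild-type MCF-7 (n = 3), MCF-7 in 100 nM fulvestrant for 8 weeks (n = 3) or 21 weeks (n = 2), and T47D given vehicle (n = 3) or 1 µM decitabine (n = 3) for 96 hours. The labels do not say that the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

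Each scanner table held 44495 spots, of which 43118 were not control spots. The authors' scanner intensity values were made with Agilent Feature Extraction (spot analysis version 9.5.3.1), and per the file headers the processed intensity was background-subtracted with spatial and multiplicative detrending switched on. The flags for spots well above background, saturated spots and outlier spots were deposited by the authors in the same tables, and no other column served as a flag. The deposited series table holds the authors' processed values of the same arrays, which are on a log2 scale judging by their correlation with the log2 scanner intensity (r between 0.965 and 0.981 across probes of each array). Its 28433 rows all matched a probe, and the column medians lay between 8.34 and 8.38. Which normalisation the authors applied to that table is not given in the sources used here, so it served only as an alternative.

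Spots of one probe were averaged after control spots and outlier spots were left out, which gave 34127 probes. At most 37 probes of an array lost all their spots. Of the probes, 25422 were named through their transcript accession in a RefSeq gene table, 1163 through the symbol in the scanner file and 382 through an older synonym. The other 7160 probes were not named here and entered no gene test. Coordinates are those the scanner files give for the probes on hg19. No annotation of that build was used, so whether a probe lies in an exon, an intron or a UTR is not given here.

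The processed intensity was taken to log2, and the 75th percentile of each array was subtracted. Levels below are on this scale. The 75th percentile ranged from 1562 to 5472 intensity units, with ED1 the brightest, and between 65.5% and 85.1% of probes were well above background on an array. A probe was kept where it was well above background on every array of at least 1 group, which left 29322 probes. Each gene was represented by its kept probe with the highest mean, which gave 18232 genes, of which 4715 had more than 1 kept probe. For some named genes the values of other probes are given as well. These, and the genes named because they were called without being well above background in either group, were chosen after their values were seen. For decitabine 53 genes called higher and 74 called lower were of that kind, for T47D fulvestrant 129 and 32, for ED1 3 and 185, for ED2 42 and 43, for estradiol 46 and 27, for 38 against 24 weeks 83 and 25, for the labelled 8 weeks 157 and 23, for 21 against 8 weeks 23 and 184, and for 21 weeks against wild type 42 and 76. The 75th percentile was 5223 and 5472 units on the ED1 arrays, against 1969 and 1592 in wild-type T47D. Subtracting it puts a given background intensity lower in ED1, so the ED1 calls of that kind may depend on array brightness. The number of arrays limits the precision.

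Tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on 1 fit over all 26 arrays with a mean per group and 15 residual degrees of freedom, so that groups of 2 shared the estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. Where the probe was not well above background on any array of a group, or was saturated on all of them, only a bound is given, as "at least N-fold". That bound sets the mean of the brighter group against the mean, over the dim arrays, of the higher of the lowest signal among probes well above background and the dim probe's own signal.

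For shifts of gene groups, 22 lists with 567 entries were written before the data were examined, as were the group comparisons, the alternatives and the rule for genes named in the text. They covered estrogen-induced, luminal, basal, epithelial-mesenchymal transition, stem cell, cancer-testis and germline, interferon-stimulated, antigen presentation, imprinted, reported methylated in breast cancer, proliferation, p53 and arrest, DNA methylation machinery, decitabine metabolism, cholesterol synthesis, ERBB, NF-kB and inflammatory, neural, fibroblast, immune, endothelial and housekeeping genes. Of their entries, 8 were not on the array. Only members that passed the filter on dim probes count as measured below. Each list was set against all other genes with camera at a preset correlation of 0.01, adjusted over 198 pairs of list and comparison. Of these pairs 66 were called, and 45 were also called with the correlation estimated from the data.

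The naming rule gave ESR1, PGR, GREB1, TFF1 and DNMT1 in every comparison. It added the 6 highest and 6 lowest log2 fold changes among called genes whose arrays did not overlap and that were well above background on every array of the brighter group (3 and 3 for 38 against 24 weeks of estradiol, for 21 weeks of fulvestrant against wild type and for the difference between the lines). It further took up to 4 called members per list, and the 15 genes with the largest decitabine change among those meeting all criteria of the study's design. Of these genes, 1 is not reported here.

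The fit was tested on simulated data with 200 genes changed among 18112. For decitabine against vehicle, 83% of genes changed by 1 log2 unit and 59% of those changed by 0.5 were recovered, with 7 unchanged genes called. For T47D fulvestrant against wild type the shares were 73% and 37%, with 5 unchanged genes called. The real comparisons called far more genes (8112 and 10717), so these shares and false calls may not carry over to them. Replicates correlated at r between 0.991 and 0.998 across genes, and no replicate pair held identical values. The arrays came from 9 slides scanned on 4 days. Decitabine, ED1, ED2 and the arrays labelled MCF-7 fulvestrant 8 weeks each shared a slide with arrays of their control group, and a group's slide was also entered as a fixed or random block. T47D fulvestrant and wild-type T47D shared neither slide nor scan day. The same held for 38 against 24 weeks of estradiol and for 21 weeks of fulvestrant against the labelled 8 weeks. ED2 given estradiol shared no slide with ED2, and 21 weeks of fulvestrant shared none with wild-type MCF-7. Other alternatives were normexp background correction with an offset of 50, quantile normalisation, other filters on dim probes, the median over a gene's probes, only the arrays compared, a minimum fold, each estradiol time alone, a replicate block and leaving out each array in turn. Scan day as a block, a fit without 3 arrays in doubt and crossed replicate numbers were added after seeing the data. Between the last of the 4 scan days and the others, the scan day block rests on 1 array, wild-type MCF-7 replicate 3.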

Results

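Transcript levels were measured on 26 arrays of 2 breast cancer cell lines, T47D and MCF-7, that express the estrogen receptor alpha gene ESR1 when untreated. The design text of the study asks which genes behave inversely to the receptor and are also raised by decitabine, a nucleoside that traps DNA methyltransferases and so lowers DNA methylation. Fulvestrant is an estrogen receptor antagonist that leads to loss of the receptor protein, and estradiol is its main natural ligand. The 75th percentile of the array intensities lay between 1562 and 5472 units, and 65.5% to 85.1% of probes were well above background.

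ESR1 (probe on chromosome 6, 152423908 to 152423967, hg19) fell in every T47D population grown without estrogen signalling. Its level was 1.26 ± 0.08 (SD, n = 2) in wild-type T47D, -4.72 ± 0.05 (n = 2) under fulvestrant, -7.37 ± 0.10 (n = 2) in ED1 and -3.21 ± 0.07 (n = 2) in ED2, on a log2 scale relative to the 75th percentile. In wild-type MCF-7 it was 0.75 ± 0.14 (SD, n = 3), on the arrays labelled MCF-7 fulvestrant 8 weeks -1.95 ± 0.05 (n = 3), and after 21 weeks of fulvestrant 1.99 ± 0.07 (n = 2). These are levels of 1 of 3 ESR1 probes, the one with the highest mean over the arrays. Against wild-type T47D another of the probes gave -2.19 under fulvestrant, -2.15 in ED1 and -2.32 in ED2, so the size of the fall and the differences between the populations depended on the probe. The progesterone receptor gene PGR (chromosome 11, 100900858 to 100900917), a classical target of the estrogen receptor, stood at 3.71 ± 0.20 (n = 2) in wild-type T47D and at -1.55 ± 0.23 (n = 3) in wild-type MCF-7.

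**Figure D1:**
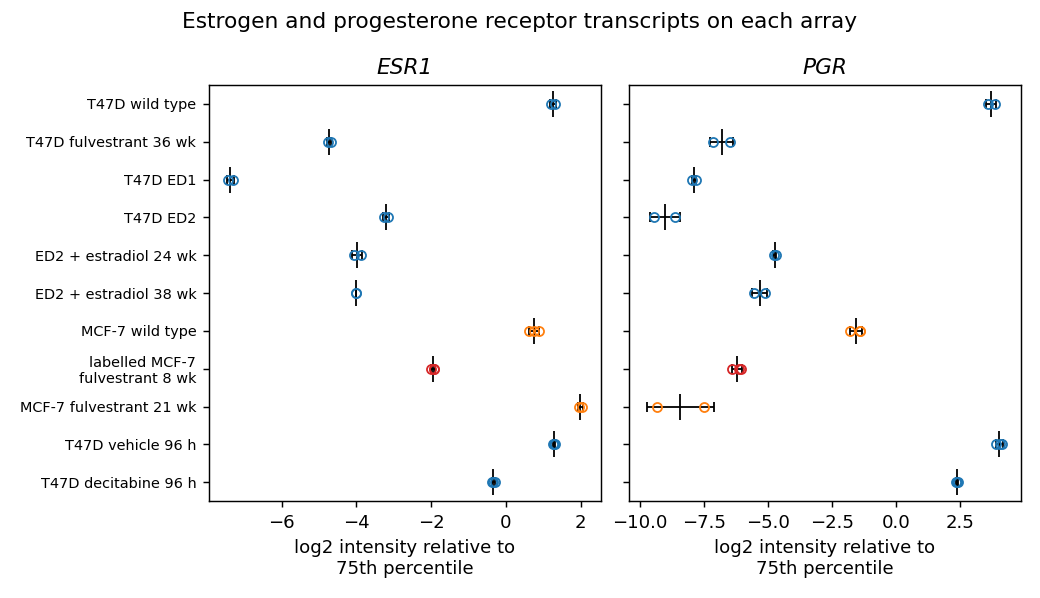
Levels of ESR1 and PGR on each array (circles; x axis, log2 intensity relative to the array's 75th percentile) by group, with the group mean (vertical mark) and SD (horizontal bar). ESR1 lies between -7.37 and -3.21 on average in the 3 receptor-low T47D populations and at 1.26 in wild-type T47D.

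The arrays labelled MCF-7 fulvestrant 8 weeks lay with the T47D arrays. MTAP (chromosome 9, 21837969 to 21854648), a purine salvage gene next to CDKN2A, was not well above background on any wild-type MCF-7 array or any array of 21 weeks. Its level was -0.74 ± 0.17 (SD, n = 3) on the labelled arrays and -0.83 ± 0.03 (n = 2) in wild-type T47D. The glutathione transferase gene GSTT1 (chromosome 22, 24376333 to 24376392) stood at 0.54 ± 0.13 (n = 3) in wild-type MCF-7 and at 1.19 ± 0.05 (n = 2) after 21 weeks. It was not well above background on the labelled arrays or in wild-type T47D. BCAS3 (chromosome 17, 59469390 to 59469449), from a region amplified in MCF-7, was at 5.38 ± 0.07 (n = 3) in wild-type MCF-7, 5.01 ± 0.04 (n = 2) after 21 weeks and -1.73 ± 0.04 (n = 3) on the labelled arrays. Across genes, which are not independent replicates, the mean of the labelled arrays correlated at r = 0.98 with T47D fulvestrant, 0.958 with wild-type T47D and 0.883 with wild-type MCF-7. All comparisons that use these 3 arrays are reported under their label.

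**Figure D2:**
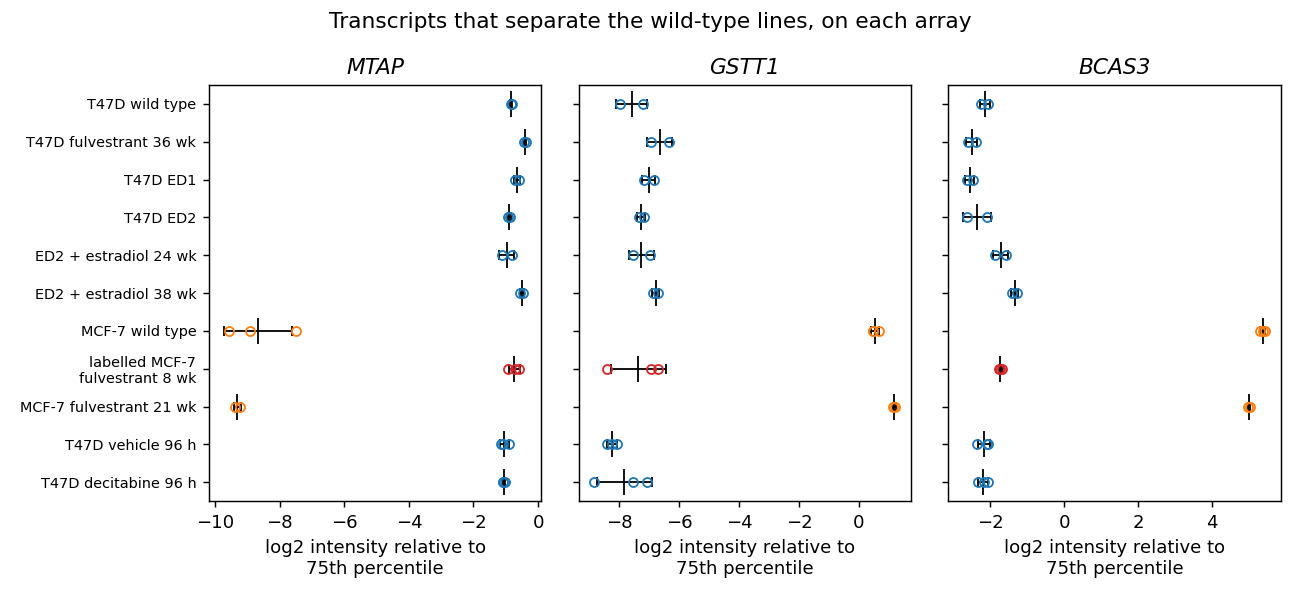
Levels of MTAP, GSTT1 and BCAS3 on each array (circles; x axis, log2 intensity relative to the array's 75th percentile) by group, with the group mean (vertical mark) and SD (horizontal bar). The arrays labelled MCF-7 fulvestrant 8 weeks (red) have a mean BCAS3 level of -1.73, against 5.38 in wild-type MCF-7 and -2.14 in wild-type T47D.

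The comparison of decitabine with vehicle asked which genes of T47D cells rise when DNA methylation is inhibited. After 96 hours in 1 µM decitabine, cancer-testis and germline genes, which are silent in most somatic cells, rose. Basal epithelial genes rose as well, and estrogen-induced, luminal and proliferation genes fell. TFPI2, an inhibitor of serine proteases (chromosome 7, 93516575 to 93516634), rose at least 4150-fold, to a level of 5.49 ± 0.06 (SD, n = 3). PAGE2B (chromosome X, 55103897 to 55103956) and PAGE2 (chromosome X, 55117033 to 55117813), both cancer-testis antigens, rose at least 1400-fold and at least 844-fold. ESR1 itself fell by 1.62 (SE 0.07, adjusted p = 2.28e-12), with its other probes at -0.80 and -0.99, and PGR was at -1.65 (SE 0.32, adjusted p = 0.000427). A second probe of PAGE2B gave at least 158-fold.

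Of 43 measured cancer-testis and germline genes, 40 rose, none fell and 3 did not pass the test (40 rose adjusted over the list alone, camera adjusted p = 6.64e-24). A gene was measured only if well above background on every array of at least 1 group, so members dim everywhere were left out. For 22 of the 43 no array was well above background in 1 group, decitabine or vehicle, and for 0 of them this held in both. The share that rose is thus partly set by the filter. Among 27 basal genes 21 rose, 1 fell and 5 did not pass (21 and 1 adjusted over the list alone; adjusted p = 1.09e-09), led by KRT17 at 3.97 (SE 0.16), KRT14 at 3.85 (SE 0.20) and the basal regulator TP63 at 3.25 (SE 0.19) on the log2 scale. Genes of p53 response and cell cycle arrest rose in 19 of 31 cases, fell in 6 and did not pass in 6, with the same counts adjusted over the list alone (adjusted p = 0.00113), and CDKN1A, an inhibitor of cyclin-dependent kinases, rose by 2.29 (SE 0.07). Of 38 proliferation genes 29 fell and 9 did not pass (29 adjusted over the list alone; adjusted p = 4.96e-08), with sizes such as CENPA at -0.68 (SE 0.09). Among 32 estrogen-induced genes 20 fell, 4 rose and 8 did not pass (20 and 4 adjusted over the list alone; adjusted p = 0.00248), including the secreted TFF3 at -1.44 (SE 0.11) and, with another probe, -0.67. Luminal genes fell in 13 of 24 cases, rose in 5 and did not pass in 6 (14 and 7 adjusted over the list alone; adjusted p = 0.00678), a call lost under quantile normalisation (adjusted p = 0.111). Cholesterol synthesis genes fell in 14 of 25 cases, rose in 1 and did not pass in 10 (17 and 1 adjusted over the list alone; adjusted p = 0.000242), the riser being PCSK9, a regulator of the LDL receptor, at least 7.78-fold.

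Further lists were called with the preset correlation, and those calls were lost with an estimated one. Of 27 NF-kB and inflammatory genes 15 rose, none fell and 12 did not pass (15 adjusted over the list alone; adjusted p = 0.000738, and adjusted p = 0.14 with an estimated correlation), among them the calprotectin gene S100A8 at 4.64 (SE 0.15). The called CCL20 was not well above background in either group. Epithelial-mesenchymal transition genes rose in 16 of 31 cases, fell in 1 and did not pass in 14 (16 and 1 adjusted over the list alone; adjusted p = 0.00015, and adjusted p = 0.124 with an estimated correlation), with vimentin, VIM, at 3.11 (SE 0.12). Genes reported methylated in breast cancer rose in 14 of 31 cases, fell in 6 and did not pass in 11, with the same counts adjusted over the list alone (adjusted p = 0.0114, and adjusted p = 0.129 with an estimated correlation). Their median of 0.04 turned to -0.04 under normexp. In that list of genes GSTP1, a glutathione transferase, rose by 8.14 (SE 0.12). Stem cell genes rose in 14 of 26 cases, fell in 4 and did not pass in 8 (15 and 4 adjusted over the list alone; adjusted p = 0.0218, and adjusted p = 0.0906 with an estimated correlation). Immune cell markers rose in 7 of 13 cases and did not pass in 6 (7 adjusted over the list alone; adjusted p = 0.0252, and adjusted p = 0.492 with an estimated correlation), led by the lipopolysaccharide co-receptor CD14 at 3.38 (SE 0.23). Of 13 genes of decitabine uptake and metabolism 8 fell, 1 rose and 4 did not pass, with the same counts adjusted over the list alone (adjusted p = 0.0411, and adjusted p = 0.172 with an estimated correlation). That call was lost under normexp (0.142), quantile normalisation (0.106) and slide as a random block (0.216). The activating kinase DCK was at -0.66 (SE 0.13), and the deaminase CDA, which inactivates the drug, rose by 2.28 (SE 0.20).

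In all, limma called 4300 genes higher and 3812 lower among 18231 (8112 called), of which 1942 and 310 changed at least 2-fold. Among the largest falls were GALNT5, a mucin-type glycosyltransferase, by 2.68 (SE 0.38), the ketogenic enzyme gene HMGCS2 by 2.39 (SE 0.34) and SORBS2, a cytoskeletal adaptor, by 2.26 (SE 0.13). Another SORBS2 probe was at -0.14 (adjusted p = 0.597), and DNMT1, the maintenance methyltransferase, was at -0.14 (SE 0.12, adjusted p = 0.366). TFF1 fell by 0.55 (SE 0.15, adjusted p = 0.00682) and GREB1, another estrogen target, by 0.65 (SE 0.20, adjusted p = 0.0154). GREB1 lost its call with slide as a fixed block, at -0.61 (SE 0.24, adjusted p = 0.0698). With slide as a fixed block 6925 genes were called, and on the slide that held arrays of both groups 8105 of the 8112 called genes had the same direction. The arrays of that slide also entered the calls, so this is no independent check. The cancer-testis median on that slide was 4.32 and the basal median 1.41. Over all arrays these medians were 4.30 and 1.23, but 1.69 and 0.65 under normexp and 1.85 and 0.72 in the deposited table. With members not well above background in a group set at their bound they were 2.94 and 0.98.

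The T47D comparisons with fulvestrant and with 52 or 62 weeks without estrogen asked which genes rise when the receptor is low. In T47D kept in fulvestrant for 36 weeks, estrogen-induced genes fell and interferon-stimulated, inflammatory and basal genes rose. ESR1 fell by 5.98 (SE 0.08, adjusted p = 1.07e-18) with the probe of highest mean, while the others were at -2.19 (SE 0.14) and at least 25.3-fold lower. PGR fell by 10.52 (SE 0.40, adjusted p = 3.17e-13) and was well above background on 1 of 2 fulvestrant arrays, and with another probe PGR was at least 1250-fold lower. SERPINA6, which encodes corticosteroid-binding globulin (chromosome 14, 94770630 to 94770689), fell by 9.98 (SE 0.20). The chemokine gene CXCL12 (chromosome 10, 44872888 to 44872947) fell by 9.64 (SE 0.11), but other probes of CXCL12 were at -5.03, at -0.20 (adjusted p = 0.704) and at least 513-fold lower. BPIFB1, a secreted protein of airway epithelium (chromosome 20, 31891780 to 31892659), rose at least 581-fold and the transcription factor gene TFAP2B (chromosome 6, 50815178 to 50815237) at least 299-fold.

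Of 41 interferon-stimulated genes 39 rose and 2 did not pass (39 adjusted over the list alone; camera adjusted p = 1.2e-18), with IFI27 at 8.34 (SE 0.34) and the antiviral gene RSAD2 at least 62.5-fold higher. Among 27 NF-kB and inflammatory genes 23 rose, 1 fell and 3 did not pass (24 and 1 adjusted over the list alone; adjusted p = 3.06e-08), led by LCN2, an iron-siderophore carrier, at 8.95 (SE 0.25). The called CXCL8 and PTGS2 were not well above background in either group, nor was the called basal gene KIT. Basal genes rose in 22 of 27 cases, fell in 2 and did not pass in 3, with the same counts adjusted over the list alone (adjusted p = 7.14e-08), for example KRT14 at 6.03 (SE 0.24) and KRT17 at 5.97 (SE 0.20). Antigen presentation genes rose in 17 of 25 cases, fell in 2 and did not pass in 6, again with the same counts adjusted over the list alone (adjusted p = 0.000335, and adjusted p = 0.0984 with an estimated correlation), with the class II gene HLA-DRA at least 32.4-fold higher. Of 32 estrogen-induced genes 26 fell, 3 rose and 3 did not pass (26 and 4 adjusted over the list alone; adjusted p = 5.03e-14), including the carbonic anhydrase CA12 at -8.67 (SE 0.16). Luminal genes fell in 18 of 24 cases, rose in 4 and did not pass in 2, with the same counts adjusted over the list alone (adjusted p = 5.15e-06), among them the prolactin receptor PRLR at -4.27 (SE 0.05) and, with another probe, -5.32.

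In this comparison 5903 genes were called higher and 4814 lower by limma, and the median over all genes was 0.12. GREB1 was at -2.86 (SE 0.25), and with its other probe at least 359-fold lower. TFF1 was at -2.60 (SE 0.19) and DNMT1 at -0.53 (SE 0.15, adjusted p = 0.00533). Without fulvestrant replicate 1 or without wild-type replicate 2 the DNMT1 call was lost, at -0.43 each time (adjusted p = 0.0603 and 0.0617), and with scan day as a block it was -0.25 (adjusted p = 0.375). Fulvestrant and wild-type arrays shared no slide or scan day. With scan day as a block 6898 genes were called (3170 higher, 3728 lower). The day effect behind that count rests on 1 array of the other line, wild-type MCF-7 replicate 3. Over 61 genes of short or non-polyadenylated RNA the median difference between the fulvestrant and wild-type arrays was 0.55.

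In ED1, after 52 weeks without estrogen, interferon-stimulated, basal and inflammatory genes rose and estrogen-induced genes fell. SPRR3, a component of the cornified envelope (chromosome 1, 152976230 to 152976289), rose at least 3420-fold and was saturated on both ED1 arrays. IGFBP3, an insulin-like growth factor binding protein (chromosome 7, 45952608 to 45952667), rose at least 824-fold and TFAP2B at least 1150-fold. ESR1 fell by 8.63 (SE 0.08, adjusted p = 1.44e-20) with the same probe, while the others were at -6.23 and -2.15, and PGR fell by 11.59 (SE 0.40) or, with another probe, at least 3370-fold. The G protein subunit gene GNG11 (chromosome 7, 93555764 to 93555823) fell by 10.65 (SE 0.21). CD69, an early activation antigen of lymphocytes (chromosome 12, 9905261 to 9905320), was at least 1050-fold lower, and the glucocorticoid receptor gene NR3C1 (chromosome 5, 142660729 to 142660788) at least 293-fold lower. Second probes of these genes gave at least 311-fold for CD69 and at least 33.2-fold for NR3C1.

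Interferon-stimulated genes rose in 40 of 41 cases and 1 did not pass (40 adjusted over the list alone; camera adjusted p = 2.77e-19), with IFI27 at 8.26 (SE 0.34). Of 27 basal genes 21 rose, 3 fell and 3 did not pass, with the same counts adjusted over the list alone (adjusted p = 5.96e-08), KRT6A at least 55.6-fold. Among 27 NF-kB and inflammatory genes 21 rose, 2 fell and 4 did not pass, also with the same counts adjusted over the list alone (adjusted p = 1.33e-06), with LCN2 at 8.80 (SE 0.25). Estrogen-induced genes fell in 29 of 32 cases, rose in 1 and did not pass in 2, unchanged in number when adjusted over the list alone (adjusted p = 7.17e-15), and CXCL12 was at -9.04 (SE 0.11), with other probes at -5.34, at -0.50 (adjusted p = 0.33) and at least 1390-fold lower. Luminal genes fell in 16 of 24 cases and rose in 8 (16 and 8 adjusted over the list alone; adjusted p = 0.00295), but not past the threshold under normexp (0.243) or quantile normalisation (0.0555). Of 16 housekeeping genes 12 fell, 2 rose and 2 did not pass, with the same counts adjusted over the list alone (adjusted p = 0.00666, and adjusted p = 0.285 with an estimated correlation). This call was lost under normexp (0.278), quantile normalisation (0.49) and slide as a random block (0.0584). Among its members with the largest changes, the probe of the ribosomal protein gene RPLP0 was saturated on 3 of the 4 arrays, and those of the ubiquitin gene UBC and the actin gene ACTB on 2 each.

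For ED1 limma called 5023 genes higher and 5333 lower, so that 48.5% of the calls were higher, against 28.6% under normexp, where the median over all genes was -0.33. TFF1 fell by 2.88 (SE 0.19). GREB1 was at -2.97 (SE 0.25), and with its other probe at least 970-fold lower. DNMT1 was at 0.07 (SE 0.15, adjusted p = 0.703). With slide as a fixed block 10047 genes were called. On the slide shared with wild-type T47D 10336 of the 10356 called genes kept their direction, but its arrays also entered the calls. Medians there were 3.19 for interferon-stimulated and -2.25 for estrogen-induced genes.

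ED2, after 62 weeks without estrogen, had list medians of 3.99 log2 units for interferon-stimulated and 2.81 for basal genes (3.79 and 1.94 under normexp). PTPRZ1, a receptor phosphatase of neural cells (chromosome 7, 121701290 to 121701349), rose at least 783-fold, and FOXQ1, a forkhead transcription factor (chromosome 6, 1314629 to 1314688), at least 722-fold. The squamous gene SPRR3 rose by 11.50 (SE 0.12, adjusted p = 2.32e-20). ESR1 fell by 4.47 (SE 0.08, adjusted p = 2.54e-17) with the same probe, while the others were at -4.39 and -2.32. PGR was at least 2050-fold lower and the lens filament gene BFSP2 at least 411-fold.

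All 41 interferon-stimulated genes rose (41 adjusted over the list alone; camera adjusted p = 1.72e-28), RSAD2 at least 232-fold. Antigen presentation genes rose in 20 of 25 cases, fell in 1 and did not pass in 4, with the same counts adjusted over the list alone (adjusted p = 7.73e-09), HLA-DRA at least 219-fold and HLA-DPA1 by 4.42 (SE 0.16) or, with another probe, 7.08. Of 27 basal genes 21 rose, 1 fell and 5 did not pass, with the same counts adjusted over the list alone (adjusted p = 2.95e-12), KRT14 by 9.08 (SE 0.24). Of 27 NF-kB and inflammatory genes 21 rose, 1 fell and 5 did not pass (22 and 2 adjusted over the list alone; adjusted p = 2.15e-09), for example the chemokine CXCL1 by 7.15 (SE 0.49) or, with another probe, 9.88. Epithelial-mesenchymal transition genes rose in 19 of 31 cases, fell in 7 and did not pass in 5, with the same counts adjusted over the list alone (adjusted p = 0.00561, and adjusted p = 0.271 with an estimated correlation), the transcription factor SNAI2 by 4.48 (SE 0.22). Proliferation genes fell in 31 of 38 cases, rose in 1 and did not pass in 6, again with the same counts adjusted over the list alone (adjusted p = 3.95e-05), with cyclin B1, CCNB1, at -1.27 (SE 0.13). Their median was -0.47, and that of housekeeping genes was -0.50. Under quantile normalisation these medians were -0.33 and 0.02. Estrogen-induced genes fell in 25 of 32 cases, rose in 2 and did not pass in 5, alike adjusted over the list alone (adjusted p = 7.09e-11). Of 24 luminal genes 15 fell, 5 rose and 4 did not pass (16 and 5 adjusted over the list alone; adjusted p = 0.0098), a call lost under normexp (0.066) and quantile normalisation (0.114).

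Here limma called 4358 genes higher and 5539 lower, a share of 44.0% higher against 29.9% under normexp, where the median over all genes was -0.28. GREB1 was at -3.27 (SE 0.25), and with its other probe at least 458-fold lower. TFF1 fell by 3.54 (SE 0.19), and DNMT1 was at -0.19 (SE 0.15, adjusted p = 0.292). With only the arrays of these 2 groups 6493 genes were called. With slide as a fixed block 8727 were called. On the shared slide, whose arrays also entered the calls, 9870 of the 9897 called genes had the same direction. Medians there were 4.05 for interferon-stimulated and 2.88 for basal genes.

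**Figure D3:**
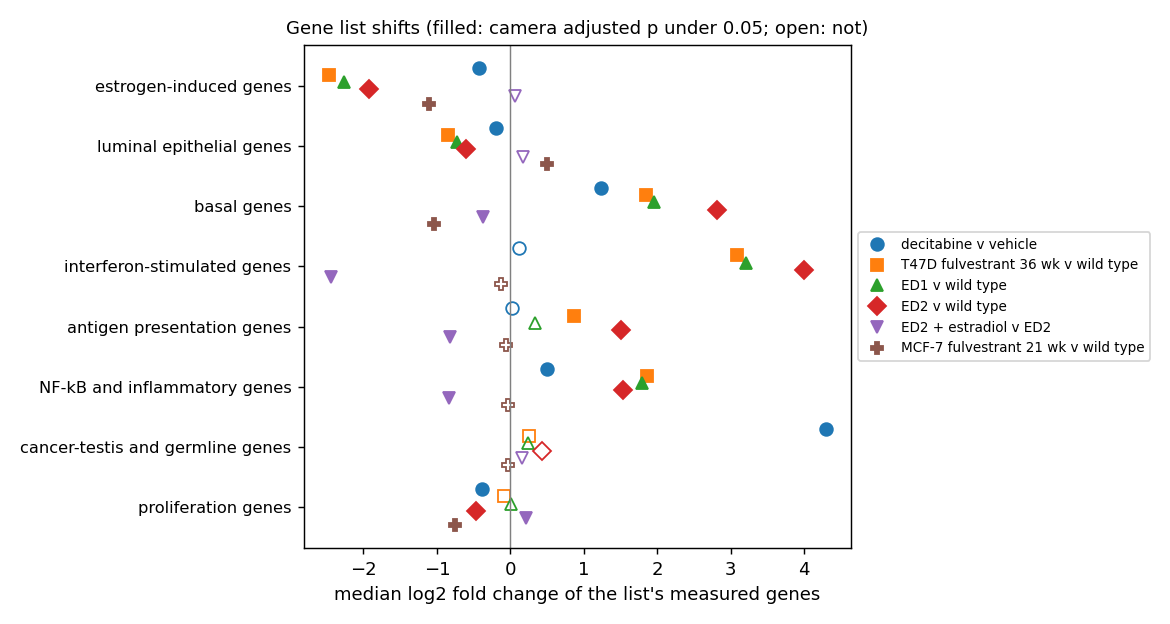
Median log2 fold change (x axis) of the measured genes of 8 lists (y axis) in 6 comparisons (symbols), filled where camera called the list. Interferon-stimulated genes have medians of 3.08, 3.21 and 3.99 in T47D fulvestrant, ED1 and ED2, and -2.44 in ED2 given estradiol.

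The 3 receptor-low populations were compared with the same 2 wild-type arrays. Across genes, fold changes of fulvestrant and ED1 correlated at r = 0.781, those of fulvestrant and ED2 at 0.739 and those of ED1 and ED2 at 0.779. Unchanged groups simulated against shared controls gave 0.501, 0.502 and 0.5. The covariances were 1.261, 1.255 and 1.45, against 0.04 in each simulation. Of genes called in fulvestrant and ED1, 3245 were higher in both and 3268 lower in both, where independent lists would share 1626 and 1408. The wild-type group cannot be divided into parts of 2 arrays, so part of the excess may come from the shared controls. Decitabine used other control arrays: 2061 genes were higher with both decitabine and fulvestrant (1392 expected from independent lists), 1914 with decitabine and ED1 (1185) and 1859 with decitabine and ED2 (1028), at r of 0.217, 0.176 and 0.215 across genes. Shared falls exceeded expectation too, with 1812 genes for fulvestrant (1007 expected), 1804 for ED1 (1115) and 2094 for ED2 (1158).

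Giving estradiol back to ED2 asked which genes the hormone lowers in these cells, and the mean of 24 and 38 weeks was set against ED2. Per the labels, no ED2 sample was kept without estradiol for those further weeks. Estradiol and time in culture therefore cannot be told apart here. Interferon-stimulated, antigen presentation and inflammatory genes fell, and the estrogen-induced list was not called in either direction. The interferon-stimulated IFI44L (chromosome 1, 79107590 to 79107649) fell by 6.74 (SE 0.47, adjusted p = 5.2e-09), RSAD2 by 6.37 (SE 0.34) and IFIT1 (chromosome 10, 91163438 to 91163497) by 5.54 (SE 0.30). TFF2, a trefoil peptide (chromosome 21, 43766648 to 43767646), rose by 4.99 (SE 0.16, adjusted p = 4.62e-13), to -0.19 ± 0.21 (SD, n = 4), and the guanylate cyclase subunit gene GUCY1A1 (chromosome 4, 156643328 to 156651224) rose by 6.59 (SE 0.36). Other probes of GUCY1A1 gave at least 5.18-fold and at least 129-fold. PGR rose at least 4.8-fold, to -5.03 ± 0.39 (SD, n = 4), while TFF1, a secreted trefoil peptide induced by estrogen, was at 0.40 (SE 0.16, adjusted p = 0.0573).

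All 41 interferon-stimulated genes fell (41 adjusted over the list alone; camera adjusted p = 1.12e-35). Of 25 antigen presentation genes 18 fell and 7 did not pass (18 adjusted over the list alone; adjusted p = 2.21e-09), with HLA-DQA1 at -3.50 (SE 0.35) and, with another probe, -2.58. Of 27 NF-kB and inflammatory genes 16 fell and 11 did not pass (16 adjusted over the list alone; adjusted p = 7.85e-08), with LCN2 at -5.08 (SE 0.22). Basal genes fell in 14 of 27 cases, rose in 2 and did not pass in 11 (17 and 2 adjusted over the list alone; adjusted p = 0.000517), KRT6A by 4.97 (SE 0.29), whereas KRT5 rose by 2.73 (SE 0.28). Stem cell genes fell in 9 of 26 cases, rose in 1 and did not pass in 16, with the same counts adjusted over the list alone (adjusted p = 0.00251), among them the Notch ligand JAG1 at -2.13 (SE 0.15). Proliferation genes rose in 19 of 38 cases, fell in 3 and did not pass in 16 (22 and 3 adjusted over the list alone; adjusted p = 0.00422, and adjusted p = 0.168 with an estimated correlation). Of 32 estrogen-induced genes 9 rose, 10 fell and 13 did not pass (11 and 10 adjusted over the list alone; adjusted p = 0.913), for example CA12 at 1.76 (SE 0.14) and the keratin KRT13 at -1.74 (SE 0.15). Their median was 0.06, their mean 0.09 and the test's direction downward.

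Here limma called 4529 genes higher and 3661 lower. The arrays with estradiol shared no slide with ED2, and those of 38 weeks were also scanned on another day than ED2. ESR1 fell further, by 0.78 (SE 0.07, adjusted p = 1.74e-07), but its other probes were at -0.05 (adjusted p = 0.745) and -0.33 (adjusted p = 0.253). GREB1 was at -0.18 (SE 0.22, adjusted p = 0.527). Its other probe was called in the opposite direction (adjusted p = 0.0275), but was not well above background in either group. DNMT1 was at -0.26 (SE 0.13, adjusted p = 0.108). TFF1 was called at 0.74 without ED2 replicate 2 (adjusted p = 0.00281), at 0.48 without replicate 2 of 24 weeks (0.0344), at 0.90 with 38 weeks alone (0.000749), at 0.36 under normexp (0.0431) and at 0.44 under quantile normalisation (0.0257). DNMT1 was called at -0.43 without ED2 replicate 2 (adjusted p = 0.0371) and at -0.37 with 38 weeks alone (0.045), and GREB1 at -0.67 with 24 weeks alone (0.0367). The changes in ED2 and on estradiol, which share the ED2 arrays, correlated at r = -0.337 across genes against -0.576 simulated, with a covariance of -0.312 against -0.04. Of genes higher in ED2, 1752 were lower on estradiol, where independent lists would share 875. The ED2 group cannot be divided into parts of 2 arrays, so part of this excess may come from the shared arrays.

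Between 24 and 38 weeks of estradiol, basal genes fell (camera adjusted p = 0.000208). Interferon-stimulated genes were called lower with the preset correlation (adjusted p = 1.29e-06, and adjusted p = 0.112 with an estimated correlation). ESR1 was at -0.04 (SE 0.08, adjusted p = 0.732), but at -0.31 under quantile normalisation (0.00692). Its other probes were both called higher, at 0.34 (SE 0.14, adjusted p = 0.0487) and 0.74 (SE 0.26, adjusted p = 0.0264). PGR was at -0.60 (SE 0.40, adjusted p = 0.223), and at -0.75 as the median over probes (0.0127). DCAF4L2, a DDB1-CUL4 associated factor (chromosome 8, 88882979 to 88883038), was higher by 6.22 (SE 0.26, adjusted p = 5.5e-10), at -0.26 ± 0.08 (SD, n = 2) against -6.49 ± 0.08 (n = 2), and at least 5.42-fold higher with another probe. The ephrin receptor gene EPHA7 (chromosome 6, 93950480 to 93950539) was at least 3.12-fold lower, and at least 1.03-fold lower with another probe (adjusted p = 0.0288). The ribosomal RNA gene RNA18SN5, for which the files give no position, was higher by 5.01 (SE 0.52) and the small nucleolar RNA SNORA74A at least 8.8-fold. Over 61 genes of short or non-polyadenylated RNA the median was 1.10, with 37 higher and 1 lower. The same genes had a median of 0.55 in T47D fulvestrant minus wild type, and of 0.41 in wild-type MCF-7 replicate 3, scanned on the day of the 38-week arrays, minus replicates 1 and 2.

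Basal genes fell in 15 of 27 cases, rose in 2 and did not pass in 10, with the same counts adjusted over the list alone (camera adjusted p = 0.000208), and KIT, called higher, was not well above background at either time. Of 41 interferon-stimulated genes 25 fell, 1 rose and 15 did not pass (25 and 2 adjusted over the list alone; adjusted p = 1.29e-06, and adjusted p = 0.112 with an estimated correlation), IFI27 by 2.60 (SE 0.34). NF-kB and inflammatory genes fell in 11 of 27 cases, rose in 4 and did not pass in 12 (14 and 4 adjusted over the list alone; adjusted p = 0.0069, and adjusted p = 0.244 with an estimated correlation). Endothelial markers rose in 6 of 8 cases (7 adjusted over the list alone) with 2 not passing, and immune cell markers in 8 of 13 (9 adjusted over the list alone) with 5 not passing. The endothelial CLEC14A and EMCN, both called higher, were not well above background at either time. Their adjusted p of 0.0238 and 0.0369 became 0.357 and 0.519 with an estimated correlation, and 0.434 and 0.98 with scan day as a block; the endothelial call was also lost under normexp (0.0531).

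For 38 against 24 weeks limma called 5158 genes higher and 4041 lower, and 4087 genes (1829 higher, 2258 lower) with scan day as a block, since both 38-week arrays were scanned on another day than the 24-week arrays. TFF1 rose by 1.01 (SE 0.19, adjusted p = 0.000315), but with scan day as a block was at 0.54 (adjusted p = 0.118). GREB1 was called higher by 0.99 (SE 0.25, adjusted p = 0.00357), but was at -0.24 under normexp and 0.15 as the median over probes. Its other probe was called lower (adjusted p = 0.0229), but was not well above background in either group. The call was lost without replicate 2 of 24 weeks (0.73, adjusted p = 0.0604), without replicate 2 of 38 weeks (0.72, adjusted p = 0.0602) and with scan day as a block (0.79, adjusted p = 0.0966). BARHL2, a homeobox gene, was at least 4.19-fold lower at 38 weeks (adjusted p = 0.00815), and its call was lost without replicate 2 of 24 weeks (adjusted p = 0.158) and with scan day as a block (-0.65, adjusted p = 0.747). DNMT1 was at -0.22 (SE 0.15, adjusted p = 0.237).

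Criterion iv of the study's design compares MCF-7 in fulvestrant for 8 weeks with wild-type MCF-7. On the arrays labelled MCF-7 fulvestrant 8 weeks, which lie with the T47D arrays (r = 0.958 with wild-type T47D against 0.883 with wild-type MCF-7), 8186 genes were called higher and 6084 lower by limma, with a median of 0.24 over all genes. PIP, a secretory protein of apocrine cells (chromosome 7, 142836745 to 142836804), was at least 28600-fold higher; it was saturated on the 3 labelled arrays and well above background on 1 of 3 wild-type arrays. The cancer-testis genes GAGE12F (chromosome X, 49218341 to 49218400) and MAGEA6 (chromosome X, 151870745 to 151870804) were at least 22300-fold and at least 7060-fold higher. A second probe of MAGEA6, well above background on all 6 arrays, was at 7.06 (SE 0.09). LXN, a carboxypeptidase inhibitor (chromosome 3, 158384316 to 158384375), and the arginine transporter gene SLC7A2 (chromosome 8, 17427847 to 17427906) were at least 2000-fold and at least 902-fold lower. Log2 fold changes were -2.70 for ESR1 (SE 0.07, adjusted p = 2.34e-16), -4.65 for PGR (SE 0.32), -2.77 for GREB1 (SE 0.20), -0.83 for TFF1 (SE 0.15) and -1.38 for DNMT1 (SE 0.12). The other probes of ESR1 gave -1.68 and -2.79, and that of GREB1 was at least 199-fold lower.

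On these labelled arrays, which lie with T47D, 40 of 41 interferon-stimulated genes were called higher and 1 lower (40 and 1 adjusted over the list alone; camera adjusted p = 8.51e-12). Of 27 NF-kB and inflammatory genes 25 were higher, 1 lower and 1 not past the test (25 and 1 adjusted over the list alone; adjusted p = 5.29e-06). Antigen presentation genes were higher in 24 of 25 cases and lower in 1 (24 and 1 adjusted over the list alone; adjusted p = 3.02e-06). Of 22 genes of the DNA methylation machinery 19 were lower, 2 higher and 1 did not pass, with the same counts adjusted over the list alone (adjusted p = 5.52e-05), DNMT3A at -3.11 (SE 0.09) and, with another probe, -1.70. Proliferation genes were lower in 30 of 38 cases, higher in 6 and not past the test in 2 (30 and 6 adjusted over the list alone; adjusted p = 3.65e-05). Estrogen-induced genes were lower in 22 of 32 cases, higher in 9 and not past the test in 1 (22 and 9 adjusted over the list alone; adjusted p = 0.00312). Basal (19 of 27 higher, 6 lower, adjusted p = 0.0141), cancer-testis (27 of 43 higher, 5 lower, adjusted p = 0.0105) and cholesterol synthesis genes (17 of 25 higher, 3 lower, adjusted p = 0.0328) were called, with 19 and 6, 26 and 5, and 17 and 3 adjusted over the list alone. The called DNMT3L, KIT, MAEL and LUZP4 of these lists were not well above background in either group. The calls of the last 3 lists were lost at adjusted p = 0.123, 0.407 and 0.0522 with an estimated correlation, and cholesterol synthesis also with slide as a random block (0.0967). With slide as a fixed block 12308 genes were called. On the slide of the labelled arrays, 14152 of the 14270 called genes had the same direction against the wild-type MCF-7 array it held. Those arrays also entered the calls, and the interferon median there was 3.78. Over all arrays that median was 4.11, but 2.73 under normexp and 3.42 with members not well above background in a group set at their bound.

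Criterion v sets 21 weeks of fulvestrant against 8 weeks. Against the arrays labelled MCF-7 fulvestrant 8 weeks, which lie with T47D, the 21-week MCF-7 arrays had 5698 genes called higher and 8096 lower by limma, with a median of -0.27 over all genes. These groups shared neither slide nor scan day. ESR1 was higher by 3.95 (SE 0.08, adjusted p = 6.62e-18), TFF1 by 2.47 (SE 0.17) and DNMT1 by 1.12 (SE 0.13), and PGR was at least 1.75-fold lower. That PGR call was lost under normexp, at -0.19 (adjusted p = 0.155). GREB1 was at -0.19 (SE 0.23, adjusted p = 0.449), with values of 1.46 under normexp, 0.58 under quantile normalisation and 2.43 as the median over its probes. Its other probe was at least 6.94-fold higher, and those of ESR1 were higher by 2.08 and 3.89. LXN and SLC7A2 were at least 8990-fold and at least 3200-fold higher, and PIP and the superoxide dismutase gene SOD3 at least 20400-fold and at least 12600-fold lower.

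Interferon-stimulated genes were lower at 21 weeks than on these labelled arrays, which lie with T47D, in 40 of 41 cases and higher in 1 (40 and 1 adjusted over the list alone; camera adjusted p = 1.63e-11). NF-kB and inflammatory genes were lower in 25 of 27 cases with 2 not past the test (25 adjusted over the list alone; adjusted p = 7.57e-06), and antigen presentation genes lower in 22 of 25 with 3 not past the test (22 adjusted over the list alone; adjusted p = 3.13e-06). Basal genes were lower in 20 of 27 cases, higher in 4 and not past the test in 3, with the same counts adjusted over the list alone (adjusted p = 0.000185), KRT14 at least 564-fold. Cancer-testis genes were lower in 25 of 43 and higher in 5 (25 and 5 adjusted over the list alone; adjusted p = 0.0152, and adjusted p = 0.431 with an estimated correlation), a call lost under normexp (0.17). DNA methylation machinery was higher in 13 of 22 cases and lower in 4 (13 and 4 adjusted over the list alone; adjusted p = 0.0191, and adjusted p = 0.229 with an estimated correlation). The p53 and arrest genes were higher in 19 of 31 and lower in 9 (19 and 9 adjusted over the list alone; adjusted p = 0.0369, and adjusted p = 0.0573 with an estimated correlation). With scan day as a block the last 2 were lost (0.0959 and 0.11), as they were with slide as a random block (0.132 and 0.226); the p53 list was also lost under normexp (0.086) and quantile normalisation (0.111). The called IL1B, KIT, DDX4, MAEL and DNMT3L of these lists were not well above background in either group. The fold changes of criteria iv and v share the labelled arrays and correlated at r = -0.889 across genes (simulated -0.446), with a covariance of -3.273 against -0.027. Both criteria were met by 6722 genes, against 3635 from independent lists. The 3 labelled arrays cannot be divided into parts of 2, so part of the excess may come from the shared arrays.

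Without those arrays, MCF-7 after 21 weeks of fulvestrant can be set against wild-type MCF-7. At 21 weeks ESR1 was higher than in wild type, PGR was not well above background, and proliferation and estrogen-induced genes fell. The ESR1 transcript rose by 1.24 (SE 0.08, adjusted p = 3.12e-10), with its other probes at 0.40 and 1.11, and TFF1 rose by 1.65 (SE 0.17, adjusted p = 3.23e-07), whereas PGR fell at least 43.9-fold and GREB1 was at -2.96 (SE 0.23) and, with its other probe, at -4.84. MAPK4, an atypical MAP kinase (chromosome 18, 48258062 to 48258121), rose at least 858-fold and the sialyltransferase gene ST6GAL1 (chromosome 3, 186796052 to 186796111) by 9.94 (SE 0.10). SULF1, a heparan sulfate sulfatase (chromosome 8, 70572195 to 70572254), fell at least 331-fold. ELOVL2, a fatty acid elongase, fell by 7.92 (SE 0.39).

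Of 38 proliferation genes 36 fell and 2 did not pass (37 adjusted over the list alone; camera adjusted p = 4.95e-12), with MYBL2 at -1.15 (SE 0.09). Estrogen-induced genes fell in 24 of 32 cases, rose in 4 and did not pass in 4, with the same counts adjusted over the list alone (adjusted p = 2.33e-06), the growth factor binding protein IGFBP4 by 4.83 (SE 0.12). Basal genes fell in 18 of 27 cases, rose in 1 and did not pass in 8 (19 and 1 adjusted over the list alone; adjusted p = 2.46e-05), the caveolin gene CAV1 by 4.82 (SE 0.16). Luminal genes rose in 14 of 24 cases, fell in 4 and did not pass in 6 (16 and 4 adjusted over the list alone; adjusted p = 0.000258), with the androgen receptor AR at 3.54 (SE 0.13). Cholesterol synthesis genes rose in 13 of 25 cases, fell in 3 and did not pass in 9, with the same counts adjusted over the list alone (adjusted p = 0.0219), a call lost with scan day (0.0642) or with slide (0.0897) as a block. Of 22 DNA methylation machinery genes 13 fell, 3 rose and 6 did not pass (14 and 3 adjusted over the list alone; adjusted p = 0.0219, and adjusted p = 0.242 with an estimated correlation), lost also with slide as a random block (0.0878). Interferon-stimulated genes rose in 13 of 41 cases, fell in 10 and did not pass in 18 (13 and 11 adjusted over the list alone; adjusted p = 0.732), with a median of -0.13 and an upward direction in the test, and SAMD9, called lower, was not well above background in either group. In this comparison limma called 3876 genes higher and 4856 lower. Its groups shared no slide. DNMT1 was at -0.27 (SE 0.13, adjusted p = 0.12), but was called at -0.36 without wild-type replicate 3 (adjusted p = 0.0436) and at -0.36 with scan day as a block (0.0285).

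To ask whether fulvestrant acted differently in the lines, the change on the arrays labelled MCF-7 fulvestrant 8 weeks was subtracted from the T47D change at 36 weeks. The labelled arrays lie with T47D and differ from T47D fulvestrant in exposure time. Since they were set against wild-type MCF-7, this contrast cannot tell an effect of the drug from a difference between the lines. With limma 5235 genes had a higher and 5662 a lower value in T47D. The heparan sulfate sulfotransferase gene HS6ST2 (chromosome X, 131760088 to 131760147) differed by 16.35 (SE 0.22, adjusted p = 2.19e-19) and the adipogenic receptor gene PPARG (chromosome 3, 12458499 to 12458558) by 15.16 (SE 0.15), while GNG11 differed by -19.81 (SE 0.27) and the iron exporter gene SLC40A1 (chromosome 2, 190425750 to 190425809) by -16.34 (SE 0.23). HS6ST2 and PPARG were not well above background on the wild-type T47D arrays, so their differences are fitted values that depend on signals near background. Other probes gave 8.85 for HS6ST2 and 13.45 for PPARG, and -0.50 and -2.51 for ESR1. ESR1 differed by -3.28 (SE 0.11), PGR by -5.87 (SE 0.51), TFF1 by -1.77 (SE 0.24) and DNMT1 by 0.85 (SE 0.19), all called, and GREB1 by -0.09 (SE 0.32, adjusted p = 0.84). GREB1 was called under normexp, at -0.76 (adjusted p = 0.00348), and as the median over its probes, at -0.49 (adjusted p = 0.0238).

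The study's candidates are genes raised by decitabine (criterion i), raised in T47D fulvestrant, ED1 and ED2 (ii), lowered by estradiol in ED2 (iii), raised on the arrays labelled MCF-7 fulvestrant 8 weeks (iv) and lower at 21 than at 8 weeks (v). By the calls of limma 4300 genes met criterion i, 1200 met i and ii, 549 met i to iii, 309 met i to iv and 280 met all; the design text states 39, with no threshold given. The last 2 criteria rest on arrays that lie with T47D (r = 0.958 with its wild type). For 6 of the 280 genes (CAPN3, CCL20, DRC2, KLHL3, KLK12 and MT1M) at least 1 criterion rests on groups in which the gene was not well above background on any array. At a minimum of 1.5-fold in each comparison 132 genes were left, and at 2-fold 74.

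Among the 15 genes of this set with the largest decitabine change were H2AB3, GSTP1, CST6, KHDC1, DUOX1, PLAT, ANKRD65, CIB2, S100A8, IGFBP3, NLRP7, MT1M, LCN2 and KRT17. MT1M was not well above background on any array of criteria iv and v. H2AB3, a testis histone variant (chromosome X, 154610889 to 154610948), rose at least 323-fold with decitabine. It rose at least 1.63-fold under fulvestrant, at least 1.62-fold in ED1 and at least 2.71-fold in ED2, and fell by 0.80 (SE 0.22) on estradiol. GSTP1 (chromosome 11, 67354050 to 67354109) rose by 8.14 (SE 0.12) with decitabine, 5.83 (SE 0.14) under fulvestrant, 1.79 (SE 0.14) in ED1 and 3.85 (SE 0.14) in ED2, and fell by 2.79 (SE 0.12) on estradiol. The protease inhibitor gene CST6 (chromosome 11, 65780838 to 65780897) rose at least 72.3-fold with decitabine, and by 3.22 (SE 0.24), 2.81 (SE 0.24) and 1.23 (SE 0.24) in the 3 populations, and fell by 2.54 (SE 0.20) on estradiol. KHDC1 (chromosome 6, 73951862 to 73951921) rose at least 94.4-fold with decitabine, and by 3.21, 1.47 and 1.18 (SE 0.32 each) in the populations, and fell by 0.74 (SE 0.27, adjusted p = 0.0359) on estradiol. DUOX1, an NADPH oxidase (chromosome 15, 45457629 to 45457688), rose at least 18.2-fold with decitabine, at least 5.54-fold under fulvestrant and at least 1.2-fold in ED2, and was at least 1.46-fold lower on estradiol. Its call in ED1 (adjusted p = 7.93e-06) gave no bound above 1, since DUOX1 was not well above background in wild-type T47D. The plasminogen activator gene PLAT (chromosome 8, 42032812 to 42032871) rose at least 42.8-fold with decitabine, at least 2.65-fold, at least 2.04-fold and at least 12-fold in the populations, and fell by 0.63 (SE 0.13) on estradiol.

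On the labelled arrays, which lie with T47D, these 6 genes were higher than in wild-type MCF-7 by between 0.44 (CST6, SE 0.19, adjusted p = 0.0469) and 7.29 (GSTP1, SE 0.12). Of the fixed lists, interferon-stimulated genes held 14 of the 280, among them ISG15, IFI27 and MX1. Criteria ii to v each called 39 to 41 of the 41 genes of that list in their direction, and decitabine raised 14 of them without a call of the list (camera adjusted p = 0.264). NF-kB and inflammatory genes held 10, such as NFKBIA and ICAM1. Basal genes held 7, among them KRT14 and TP63, and antigen presentation genes 3, namely HLA-E, TAP1 and HLA-DRB1. A fit without the labelled arrays left 550 genes for criteria i to iii, of which 272 were among the 280. Criteria i to iii use none of the labelled arrays, and the 280 lie within the 549 genes that met them. This overlap was therefore largely fixed in advance and does not test criteria iv and v.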

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

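The slide test and the test on genes of 9p21 were chosen only after the result was seen, as was scan day as a block.

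By the labels, the effect of fulvestrant differed between T47D at 36 weeks and the arrays labelled MCF-7 fulvestrant 8 weeks for 10897 genes. This drew attention because the difference between the groups itself passed limma's test. Arrays that lie with T47D were here set against wild-type MCF-7, so drug and line cannot be told apart. HS6ST2 differed by 16.35 (7.51 in T47D, -8.84 on the labelled arrays), PPARG by 15.16 (6.75 and -8.40) and RERGL by 12.53 (9.92 and -2.61). GNG11 differed by -19.81 (-8.28 and 11.52), SLC40A1 by -16.34 (-3.10 and 13.25) and CRH by -15.88 (-6.72 and 9.15). HS6ST2, PPARG and RERGL were not well above background in wild-type T47D, HS6ST2 was not on the labelled arrays and CRH was not in T47D fulvestrant, so their values are fitted ones that depend on signals near background. Another probe of HS6ST2 gave 8.85.

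These values draw on arrays that lie with T47D: of 245 genes well above background on every T47D array and on no wild-type MCF-7 array, 242 were so on all 3 labelled arrays, and of 33 genes with the opposite pattern 0 were. The tables argue against a slide or scan batch, since the wild-type MCF-7 array of the same slide and day kept a slope of 0.977 on the other wild-type arrays over 2296 genes that separate the lines. They also argue against MCF-7 cells changed by fulvestrant, since the genes of 9p21, a region deleted in MCF-7, lay 6.29 log2 units above wild-type MCF-7 in the median, against 0.63 at 21 weeks. RNA of T47D cells under another label is a candidate explanation: over 34 genes of regions gained in MCF-7 the slope was 0.01, against 0.989 at 21 weeks and -0.036 in T47D fulvestrant. Whether a label changed, and which T47D cells these might then be, stays open.

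The 2 times of estradiol in ED2 differed for 9199 genes, again by limma's test of the difference. DCAF4L2 differed by 6.22 (2.64 against ED2 at 24 weeks, 8.86 at 38 weeks), RNA18SN5 by 5.01 (-2.64 and 2.37) and SNORA74A by 4.79 (-0.95 and 3.85). EPHA7 differed by -3.83 (-1.38 and -5.21), MAGEB6 by -3.60 (-1.12 and -4.71) and BARHL2 by -3.34 (0.68 and -2.66). The values of SNORA74A, not well above background at 24 weeks, and of EPHA7, MAGEB6 and BARHL2, not well above background at 38 weeks, are fitted ones that depend on signals near background. As bounds, SNORA74A was at least 8.8-fold higher at 38 weeks, EPHA7 at least 3.12-fold (at least 1.03-fold with another probe), MAGEB6 at least 3.45-fold and BARHL2 at least 4.19-fold lower. DCAF4L2 was not well above background in ED2, so its values against ED2 are fitted in the same way.

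Both 38-week arrays were scanned on another day than the 24-week arrays, and scan day may account for part of this difference. Over the called genes, wild-type MCF-7 replicate 3, scanned on the day of the 38-week arrays, minus replicates 1 and 2 correlated at r = 0.595 with 38 minus 24 weeks. With scan day as a block 4087 genes were called. For the 38-week arrays that block rests on 1 array of the other line, wild-type MCF-7 replicate 3. It therefore cannot decide whether scan day is the whole cause. Longer estradiol exposure stays open and cannot be told apart from longer culture. The change up to 24 weeks correlated at -0.349 with the change after it, with no shared arrays. A value below 0.1 had been set to count against longer exposure, but that bound was wrong by design. A change that turns back between 24 and 38 weeks is also a change with time, and no other times were measured.

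For groups of 3 against 3, the arrays allow 10 splits, so the share of splits cannot go under 0.05. For decitabine, 1 of the 10 splits reached the real count of 8112 genes, and the highest other split gave 1 gene. For the arrays labelled MCF-7 fulvestrant 8 weeks, which lie with T47D, 1 of the 10 splits reached 14270 genes, and the highest other gave 1.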

How the results depend on the processing

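Scan day as a block, the fit without the arrays labelled MCF-7 fulvestrant 8 weeks and the crossed replicate numbers were chosen only after the data were seen. Of 228 counts under other settings, 211 lay within 1.5 times the reported count. Of 2696 values of 149 named gene results, 2647 kept direction and side of the threshold, 20 newly passed it, 22 no longer did and 7 turned. Apart from ESR1, PGR, GREB1, TFF1 and DNMT1, these genes were picked for large called changes in the same data. Much of this stability is therefore built in. A required change of 2-fold left 2252 genes for decitabine, 3658 for T47D fulvestrant, 3768 for ED1, 3467 for ED2, 1343 for estradiol in ED2, 2085 for 38 against 24 weeks, 7157 for the labelled 8 weeks, 7088 for 21 against 8 weeks, 2311 for 21 weeks against wild type and 6020 for the difference between the lines, by construction of the setting. Of the 280 genes meeting all criteria 74 were left at 2-fold and 132 at 1.5-fold. A 2-fold change with no test was met by 77 genes, 74 of them among the 280. A fit without the labelled arrays gave 550 genes for criteria i to iii, 272 of them among the 280. Criteria i to iii use none of those arrays, so this overlap was largely fixed in advance. Basal medians of 1.84 in T47D fulvestrant and 1.96 in ED1 were 0.91 and 0.95 under normexp. With only the arrays compared ED2 gave 6493 genes, from fewer arrays. With scan day as a block T47D fulvestrant gave 6898 and 38 against 24 weeks 4087. GREB1 turned in 38 against 24 weeks to -0.24 under normexp and -0.08 in the deposited table, and in 21 against 8 weeks to 1.46 under normexp, 0.58 under quantile normalisation, 1.84 in the deposited table and 2.43 as the median over probes. ESR1 turned to 0.34 in 38 against 24 weeks as the median over probes. The causes of these turns were not tested.

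Leaving out each array in turn gave 7151 to 7490 genes for decitabine, 8716 to 10038 for T47D fulvestrant, 8902 to 9648 for ED1, 8767 to 9285 for ED2, 6435 to 7757 for estradiol, 6765 to 8037 for 38 against 24 weeks, 13408 to 14566 for the labelled 8 weeks, 12427 to 13583 for 21 against 8 weeks, 7267 to 8976 for 21 weeks against wild type, 10223 to 11204 for the difference between the lines and 231 to 324 meeting all criteria. An array left alone in its group was assumed to vary like the other groups. With the replicate number as a block 8071 genes were called for decitabine, 10599 for T47D fulvestrant, 10331 for ED1, 9842 for ED2, 8128 for estradiol, 9125 for 38 against 24 weeks, 14211 for the labelled 8 weeks, 13430 for 21 against 8 weeks, 8533 for 21 weeks against wild type, 10852 for the difference between the lines, and 281 met all criteria. Arrays of one number deviated together at r of 0.010, -0.048 and -0.001 for decitabine and 0.155, -0.015 and 0.223 for the labelled 8 weeks, and 1 of 6 and 4 of 6 arrays correlated best with their own number, so the numbers were not taken as pairs. With the ED2 numbers crossed (r = -0.279 with 24 weeks) 9970 genes were called for ED2 and 8337 for estradiol. Slide as a random block (correlation 0.386) left 234 genes meeting all criteria, 230 of them among the 280, and normexp 191, of which 175 were. Under normexp the median over all genes was 0.12 for estradiol and -0.16 for the difference between the lines. Between 65.5% and 85.1% of probes were well above background on an array, and the others limit low levels to bounds.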

Other observations

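The comparisons of the labelled arrays with T47D and of the wild-type lines were chosen only after the data were seen, unlike the test against matched sets.

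Further gene groups were not called as lists with decitabine, although single members rose. Of 22 imprinted genes 9 rose, 6 fell and 7 did not pass (9 and 6 adjusted over the list alone; camera adjusted p = 0.287), among them MEST at 7.11 (SE 0.58) and the non-coding RNA H19 at 3.30 (SE 0.12). Neural genes rose in 7 of 15 cases and fell in 3 (7 and 3 adjusted over the list alone; adjusted p = 0.157), fibroblast markers rose in 4 of 9 (4 adjusted over the list alone; adjusted p = 0.0671) and ERBB receptors and ligands rose in 6 of 14 and fell in 2 (6 and 2 adjusted over the list alone; adjusted p = 0.419). Endothelial markers rose in 2 of 8 cases (adjusted p = 0.79), EMCN being called lower without being well above background in either group, and housekeeping genes fell in 5 of 16 (3 adjusted over the list alone; adjusted p = 0.0647). Interferon-stimulated genes rose in 14 of 41 cases and fell in 8 (14 and 8 adjusted over the list alone; adjusted p = 0.264), and antigen presentation genes rose in 10 of 25 and fell in 1 (10 and 2 adjusted over the list alone; adjusted p = 0.313), the latter being HLA-DRA. Neither HLA-DRA nor CHGB, a called neural gene, was well above background in either group. DNA methylation machinery rose in 6 of 22 cases and fell in 5 (adjusted p = 0.913), with DNMT3B at 1.02.

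The arrays labelled MCF-7 fulvestrant 8 weeks can also be set against the T47D arrays they lie with. Against wild-type T47D 6432 genes were higher and 5159 lower by limma, and against T47D fulvestrant at 36 weeks 3460 were higher and 3471 lower. ESR1 was at -3.21 (SE 0.08) against wild-type T47D and 2.77 (SE 0.08) against T47D fulvestrant, PGR at -9.91 (SE 0.36) and 0.61 (SE 0.36, adjusted p = 0.213), and TFF1 at 2.88 (SE 0.17) and 5.48 (SE 0.17). Of the 280 genes that met all criteria, 138 were called higher in wild-type T47D than in wild-type MCF-7 and 87 lower. Of 269 genes that met criteria i to iii but not both iv and v, 4 were called higher in wild-type T47D and 246 higher in wild-type MCF-7. Criterion iv sets arrays that lie with T47D against the same wild-type MCF-7 arrays, so this split is largely fixed by the criterion. At 21 weeks against wild-type MCF-7, 124 of the 280 and 126 of the 269 genes were called lower.

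Genes raised 2-fold or more by decitabine (1942 genes) had medians of 0.70 under fulvestrant, 0.51 in ED1 and 0.45 in ED2, in T47D populations that share no array with that comparison. A low starting level was tested as the explanation with 1000 random sets matched on the vehicle level. The tables argue against it as the whole cause: the matched medians were 0.53, 0.36 and 0.08, and the percentile of the real set was 100 in each population. With an estimated correlation camera did not call this set (adjusted p = 0.117, 0.24 and 0.078), while 310 genes lowered 2-fold or more had medians of -0.41, -0.35 and -0.46 (adjusted p = 0.0291, 0.0313 and 0.0313 with an estimated correlation). A shared loss of DNA methylation might account for part of this, but methylation was not measured here and stays untested.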
